A study of Arabidopsis thaliana with 4 samples.

How the data were processed

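RNA from leaves of 3-week-old wild-type and KO-nudx19 plants was hybridised to Affymetrix ATH1 arrays, with 1 array per sample, 4 arrays in all. The values used were the authors' deposited intensity signals, 1 per probe set and array. Per the submitters' processing notes, GCOS (the array maker's software, version not given) was used. The background correction, the way probes were summarised and the scaling target are not given in the sources used here. The deposited values were positive, linear, and had a mean of 200 on every array once the highest and lowest 2% were left out, as scaling each array to a common mean gives. Detection calls were not used here, and no pair of arrays shared more than 1 exactly equal value. Such scaling makes the average signal equal between arrays and leaves differences in the spread of signals, such as those of the brightest probe sets, in place.

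Groups were taken from the sample titles, and every column was matched to its sample by its identifier. The design, the tests, the gene lists and the rule for named genes were chosen before the data were examined. All signals below the 20th percentile of all values (8.92) were set to it, log2 was taken, 64 control probe sets were left out, and probe sets whose mean signal over all arrays lay below the 40th percentile (38.2) were left out, which left 13648. KO-nudx19 was compared with wild type by limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with a trend) and Benjamini-Hochberg adjustment, with an adjusted p of 0.05 as the threshold. Fold changes are on this floored log2 scale, which understates the change of dim transcripts. An exact test of a single probe set with 2 against 2 arrays cannot go below a two-sided p of 0.333, so only limma's test, which shares the spread over probe sets, was used.

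Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, for lists with at least 5 tested probe sets, and again with an estimated correlation and with fry. Of 25 lists fixed beforehand, 3 had enough tested probe sets, because the probe table named few of their genes: 73 of 473 different loci had a named probe set. A further 10 lists were added after seeing the data: plastid-encoded and mitochondrion-encoded genes, and 8 gene families taken by symbol. These were adjusted apart from the fixed ones, and the result of 1 of the families is not reported here.

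Probe sets were named through a table of the array platform's annotation, with symbols updated through gene identifiers in the RefSeq annotation of TAIR10.1. Of 22810 probe sets, 13513 named 1 gene, 503 named several and 8730, control probe sets not counted, are unnamed here. Of those with 1 gene, 13436 were matched to RefSeq and 77 kept the table's symbol. No coordinates are given, since the deposited values name no genome build. NUDX19 and the other Nudix hydrolases had no named probe set and were not analysed here. Named genes were, for each direction, up to 12 passing genes, and because none passed, the 6 in each direction with the largest gap between the nearest values of the 2 genotypes. Of each list up to 4 members were named, those that passed or, where fewer than 2 passed, those with the largest difference whose genotypes did not overlap. A gene with several probe sets was named from the brightest one, and probe sets with several genes or none were not named.

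The poly(A) controls differed between the arrays numbered 1 and those numbered 2 in both genotypes, so the replicate number was treated as a batch found in the values. The labels do not say what the number stands for. Results are given without it, as chosen beforehand, and with it as a block and within each number where this changed a result. The alternatives run were quantile normalization, centring on the median, no floor, a floor at the 40th percentile, a pseudocount equal to the floor, no filter, a filter at the 60th percentile, eBayes without a trend and with robust fitting, the replicate block, 1 probe set per named gene, and leaving out each array. Quantile normalization together with the replicate block was added after seeing the data. The code was tested on simulated arrays made from the mean signals, replicate-number differences and spread of these data, in 5 simulations of 13648 probe sets, of which 200 were changed by 2-, 4- or 8-fold. Figures were drawn with matplotlib 3.10.9.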

Results

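Leaf transcripts of wild-type Arabidopsis thaliana (accession Col-0) and of KO-nudx19 plants were measured on 4 Affymetrix ATH1 arrays, 2 for each genotype. KO-nudx19 plants lack NUDX19, a Nudix hydrolase that cleaves NADPH. The plants grew for 1 week on medium with 3% sucrose and for 2 weeks on soil, under 16 h of light at 100 µmol m−2 s−1, and leaves were taken at 3 weeks. Each array gave a signal for 22810 probe sets. The trimmed mean signal was 200 on each of the 4 arrays, and the highest signal was 15310 and 19383 on the wild-type arrays and 20502 and 28796 on the KO-nudx19 arrays. The labels number the arrays of each genotype 1 and 2 and do not say whether these came from separately grown plants, so the p-values below measure the spread between these arrays, which may be technical. With 2 arrays per genotype the number of arrays limits the precision.

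The comparison asked which leaf transcripts differ when NUDX19 is absent. The transcript of NUDX19 itself was not analysed here, because no probe set could be assigned to it, nor to any of the 26 other Nudix hydrolases. The labels of the KO-nudx19 arrays could therefore not be checked against the targeted gene.

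No transcript passed limma's test between the genotypes when the fit left the replicate number out, and 2 unnamed probe sets passed with it as a block. Most genes named here for the widest gaps between the genotypes differed by about 2-fold. The peroxidase gene AT5G64120 (PRX71), which encodes a secreted class III peroxidase, had a signal of 123 ± 7.87 in wild type and 251 ± 51.3 in KO-nudx19 (SD, n = 2 each), a log2 difference of 1.02 (SE 0.27). PME61, a pectin methylesterase of the cell wall, stood at 276 and 251 in wild type and 156 and 118 in KO-nudx19, a log2 difference of −0.95 (SE 0.27). The chloroplast and stress genes that lay apart between the genotypes did so by smaller or less even amounts.

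Of 13648 probe sets tested with limma without the replicate number, 0 passed an adjusted p of 0.05, the lowest adjusted p was 1.00, and 89 had an unadjusted p under 0.05. Independent arrays would give 682 by chance, but same-numbered arrays deviated together (correlation 0.553 over probe sets). With the replicate number as a block, 2 probe sets passed (lowest block adjusted p = 0.0459) and 738 had an unadjusted p under 0.05. The 95% confidence interval of a log2 difference had a median half-width of 0.76 without the block, that is 1.70-fold, and of 0.52 with it, that is 1.43-fold, so differences of that size were not excluded for a typical probe set. In simulated arrays with the spread and the replicate-number differences of these data, limma without the block recovered 0% of the probe sets changed 2-fold, 6.67% of those changed 4-fold and 54.3% of those changed 8-fold. With the block it recovered 64.8% of those changed 2-fold and 99.7% of those changed 4-fold, with 74 false calls over 5 simulations against 0 without the block. The simulated spread came from the block fit, with no shift of a single array. Recovery with the block may therefore be overstated for these arrays.

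The signals of 3044 probe sets did not overlap between the genotypes, 22.3% of those tested. Chance gives 33.3% for 2 against 2 independent arrays, while the arrays parted by replicate number gave 54.4% and the remaining split, each wild-type array with the KO-nudx19 array of the other number, gave 23.3%, close to the genotype's share. Of the 3044, 2 probe sets, both unnamed here and both higher in KO-nudx19, lay apart by at least 2-fold. The 6 named genes with the widest gap in each direction were taken as examples, and none of them passed the test, with or without the block. Higher in both KO-nudx19 arrays were AT1G36940, with 26.8 ± 1.99 in wild type and 58.1 ± 5.64 in KO-nudx19, AT5G27860, with 39.9 ± 0.292 and 78.4 ± 8.00, and AT5G20400, with 32.1 ± 0.763 and 65.0 ± 10.3. AT1G69610 had 26.0 ± 5.07 in wild type and 52.5 ± 2.34 in KO-nudx19, and AT2G23680 had 25.6 ± 1.66 and 53.5 ± 12.5. These 5 had wild-type signals below the mean of 38.2 used to leave out dim probe sets, or close to it, while AT5G64120 was brighter. With the floor on signals raised to the 40th percentile, the log2 differences of AT1G36940, AT1G69610 and AT2G23680 were 0.64, 0.50 and 0.51, against 1.11, 1.03 and 1.04.

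Lower in both KO-nudx19 arrays, beside PME61, were AT3G59780, with 643 ± 107 in wild type and 324 ± 19.0 in KO-nudx19, and AT5G47050, with 78.1 ± 2.62 and 34.8 ± 6.73. Their log2 differences were −0.98 (SE 0.25) and −1.18 (SE 0.35). AT3G51530 had 67.0 ± 6.61 in wild type and 37.4 ± 3.21 in KO-nudx19, and AT1G23410 had 89.6 ± 4.21 and 54.1 ± 3.00. AT5G48210 had 80.3 and 70.0 on the wild-type arrays but 2.21 and 42.2 on the KO-nudx19 arrays. Its log2 difference of −1.95 (SE 0.75) rests largely on KO-nudx19 replicate 1, whose value lay below the floor of 8.92 set on all signals. It was −0.83 without that array and −3.07 without KO-nudx19 replicate 2, and −2.96 with no floor and −0.92 with the floor at the 40th percentile.

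**Figure D1:**
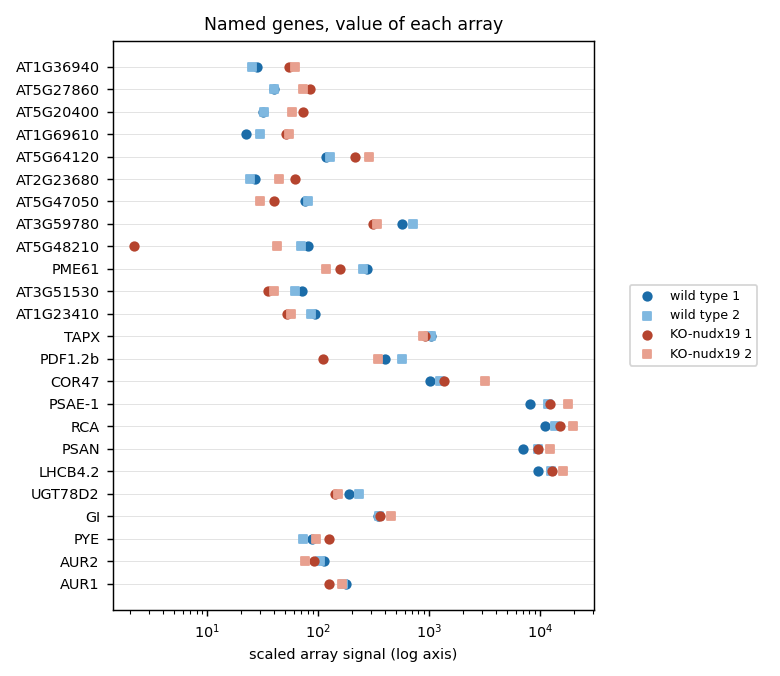
Scaled signal (log axis) of the 24 genes named by rule, with 1 point per array; blue points are wild type and red points KO-nudx19, circles replicate 1 and squares replicate 2. Blue and red points do not overlap for any of these genes, because the rule took only such genes. None passed the limma test. The gap is widest for genes such as AT1G36940, with 28.2 and 25.4 in wild type against 54.1 and 62.1 in KO-nudx19.

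Photosynthesis genes encoded in the nucleus had higher signals in KO-nudx19 as a group, a shift that passed at a preset correlation between genes and not in other tests. Of 9 probe sets tested, 7 had a log2 difference above 0 and 2 below, 5 did not overlap between the genotypes, all higher in KO-nudx19, and 0 passed limma's test, over all genes or adjusted over the list alone. The gaps of these 5 ranged from 1.01-fold (PSAN) to 1.14-fold (PRK). LHCB4.3, the dimmest member, had 406 ± 140 in wild type and 318 ± 218 in KO-nudx19, a log2 difference of −0.50. The photosystem I subunit gene PSAE-1 had 9934 ± 2554 in wild type and 14954 ± 3955 in KO-nudx19, and PSAN had 8235 ± 1817 and 10891 ± 1830. RCA, which encodes Rubisco activase, had 12412 ± 1836 and 17234 ± 3262, and the antenna gene LHCB4.2 had 10986 ± 2087 and 14466 ± 2461 (SD, n = 2 each, none passing). The list's median log2 difference was 0.39, with a camera adjusted p of 8.6e-04, and it was 0.43 for the arrays numbered 1 and 0.36 for those numbered 2. The call was lost with an estimated correlation (adjusted p = 0.663), and after quantile normalization the median was −0.015 (adjusted p = 0.696), where RCA stood at −0.015, LHCB4.2 at −0.059, PSAN at 0.05 and PSAE-1 at 0.11. Without wild type replicate 1 the median was 0.18 (adjusted p = 0.843) and without KO-nudx19 replicate 2 it was 0.23 (adjusted p = 0.481). Leaving out single arrays, PSAE-1 ranged from 0.32 to 0.86, RCA from 0.27 to 0.66, PSAN from 0.18 to 0.64 and LHCB4.2 from 0.20 to 0.59. The hybridisation controls (bioB, bioC, bioD and cre), targets that do not come from the plant, moved with the same split. Their geometric mean was 620 and 411 on the wild-type arrays and 1054 and 1140 on the KO-nudx19 arrays.

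Neither NADPH-producing enzymes nor antioxidant enzymes passed the list test, which covered only 5 of 19 and 7 of 38 list members. Of the 5 probe sets of NADPH-producing enzymes tested, 1 had a log2 difference above 0 and 4 below, with a median of −0.06 (camera adjusted p = 0.620). The cytosolic isocitrate dehydrogenase gene cICDH had signals of 3524 and 2809 in wild type and 3426 and 2839 in KO-nudx19, and the 6-phosphogluconate dehydrogenase genes AT1G64190, AT3G02360 and AT5G41670 had log2 differences of −0.06, −0.14 and −0.16. Of the 7 antioxidant enzymes tested, 2 were above 0 and 5 below, with a median of −0.10 (camera adjusted p = 0.620). TAPX, the thylakoid ascorbate peroxidase, was the only one whose arrays did not overlap, with 1035 ± 6.67 in wild type and 900 ± 28.5 in KO-nudx19, a log2 difference of −0.20 (SE 0.22). Of 2 tested genes of NAD synthesis, QPT had a log2 difference of −0.06 and AT1G55090 of 0.34 (−0.02 for the arrays numbered 1 and 0.71 for those numbered 2). In limma none of these list members passed, over all genes or adjusted over the list alone.

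The remaining fixed lists had at most 4 tested probe sets each and were too small for a list test. The 4 jasmonate genes had log2 differences below 0 between the genotypes, with a list median of −1.47 for the arrays numbered 1 and −0.25 for those numbered 2. Among the latter, PDF1.2 and JMT stood at 0.22 and 0.27, and the mean signal of JMT was 47.0 in wild type and 47.4 in KO-nudx19. Only the defensin gene PDF1.2b had arrays that did not overlap, with 482 ± 122 in wild type and 226 ± 165 in KO-nudx19 (log2 difference −1.29, SE 0.55). This was −0.47 without KO-nudx19 replicate 1 and −2.12 without KO-nudx19 replicate 2. Its near-identical copy PDF1.2 had 380 and 403 in wild type but 61.1 and 470 in KO-nudx19, and the values of such copies are uncertain because probes can detect both. COR47, a dehydrin gene of the abscisic acid and dehydration list, had 1024 and 1247 in wild type and 1357 and 3208 in KO-nudx19, a log2 difference of 0.88 that was 0.26 without KO-nudx19 replicate 2 and 1.51 without KO-nudx19 replicate 1. UGT78D2, a flavonoid glucosyltransferase, had 211 ± 31.9 and 147 ± 7.51, and the other 2 flavonoid genes tested, DFR and AT4G14090, overlapped. PYE, a regulator of iron responses, had 79.9 ± 10.2 and 110 ± 21.7, the clock gene GI had 350 ± 4.45 and 403 ± 63.0, and the mitotic kinase genes AUR2 and AUR1 had 108 ± 5.61 and 172 ± 5.50 in wild type against 83.5 ± 10.1 and 146 ± 27.7 in KO-nudx19. The log2 differences of PYE (0.45), GI (0.20) and AUR1 (−0.26) were 0.25, 0.36 and −0.061 without KO-nudx19 replicate 1 and 0.66, 0.037 and −0.45 without KO-nudx19 replicate 2. No tested gene of cold response, salicylic acid defence, oxidative stress response, gibberellin, photoprotection, glucosinolate synthesis, heat shock, sulfur assimilation, starvation, senescence, guard cells or vascular tissue had arrays that did not overlap. Flower and root markers had no tested probe set, and none of the named genes passed limma's test.

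Transcripts encoded in the plastid genome, a list added after seeing the data, were mostly lowest on 1 wild-type array. Their median signal was 2508 on wild type replicate 1, 556 on wild type replicate 2, 1933 on KO-nudx19 replicate 1 and 2197 on KO-nudx19 replicate 2. The photosystem II gene psbC had 7128 and 487 in wild type and 6347 and 6767 in KO-nudx19, and rbcL, the large subunit of Rubisco, had 2793 and 556 against 2184 and 2394. Some were also low on KO-nudx19 replicate 2, such as psaA, with 471 and 55.6 in wild type and 247 and 37.1 in KO-nudx19. Of 65 probe sets, 54 were lowest on wild type replicate 2, and 38 were lower there than on each other array by at least 2-fold, while ndhA, with 3184 and 3714 in wild type and 3707 and 3648 in KO-nudx19, and 10 others were not lowest there. The list's median log2 difference between the genotypes was 0.75 (camera adjusted p = 1.4e-16, lost at adjusted p = 0.509 with an estimated correlation). It was −0.18 between the arrays numbered 1 and 1.83 between those numbered 2, and without wild type replicate 2 the median turned to −0.14 (adjusted p = 0.0245). The call for the genotypes thus rested on that array. Of the 65 probe sets, 13 did not overlap between the genotypes, all higher in KO-nudx19, and 0 passed limma's test. Over all tested probe sets, 22.3% did not overlap.

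**Figure D2:**
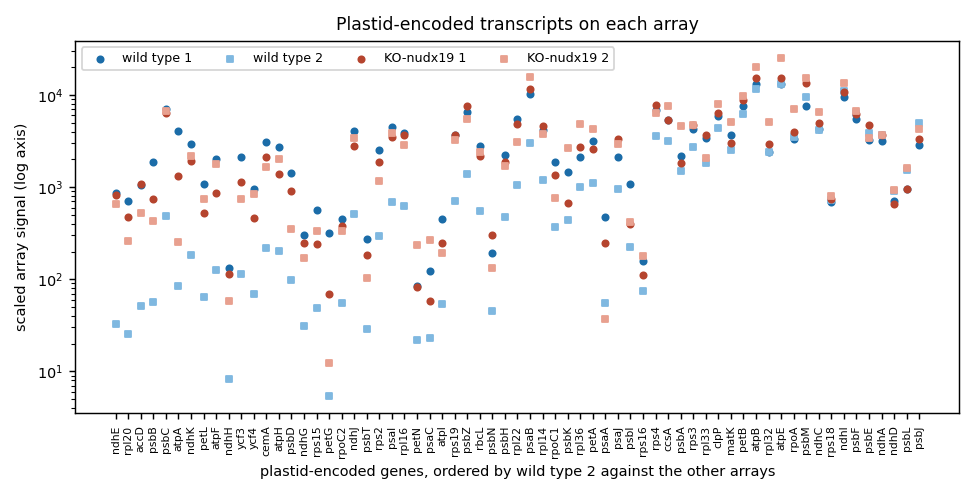
Scaled signal (log axis) of 65 plastid-encoded genes on each array, ordered by the difference between wild type replicate 2 and the other arrays; blue is wild type, red KO-nudx19, circles replicate 1 and squares replicate 2. The light blue squares of wild type replicate 2 lie lowest for 54 of the 65 genes, with a median signal of 556 against 2508, 1933 and 2197 on the other arrays.

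The arrays resembled each other by replicate number more than by genotype. The correlation of log2 signals over probe sets was 0.972 between both arrays numbered 1 and 0.965 between both numbered 2, against 0.927 between the wild-type arrays and 0.926 between the KO-nudx19 arrays. Poly(A) controls (dap, lys, phe and thr transcripts of Bacillus added to the RNA in the laboratory) had a geometric mean of 116 and 98.2 on the wild-type and KO-nudx19 arrays numbered 1, and of 19.9 and 21.0 on those numbered 2. All 24 of their probe sets were higher on both arrays numbered 1. The actin 3′/5′ ratio, a measure of RNA integrity, was 2.30 and 4.27 in wild type and 2.92 and 5.17 in KO-nudx19 (replicates 1 and 2). The GAPDH ratio was 1.01 and 1.15 in wild type and 0.986 and 1.38 in KO-nudx19, and the ubiquitin ratio 1.53 and 1.44 against 1.48 and 1.95. The log2 differences of these ratios between the genotypes were 0.31, 0.11 and 0.19, with 0.607, 0.258 and 0.199 as the SD between replicates, which holds the difference between the numbers. Within the arrays numbered 1 and 2 the actin difference was 0.35 and 0.27, that of GAPDH −0.034 and 0.26, and that of ubiquitin −0.042 and 0.43.

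With the replicate number as a term in limma, 1535 probe sets differed between the arrays numbered 2 and 1, of which 673 were higher and 862 lower on the arrays numbered 2. Centring on the median gave 1205 higher and 829 lower, so the balance of directions depended on the scaling. Genes of cold and defence responses were among those higher on both arrays numbered 2. The cold gene COR15A had 395 and 1081 in wild type and 159 and 3246 in KO-nudx19 (replicates 1 and 2, adjusted p = 4.0e-05 in limma), and COR15B had 283 and 1044 against 405 and 1602. All 4 jasmonate genes tested passed, with THI2.1, a thionin gene, at 171 and 812 in wild type and 140 and 313 in KO-nudx19. PDF1.2 hardly differed in wild type, with 380 and 403 against 61.1 and 470 in KO-nudx19. PDF1.2b, with 395 and 568 against 109 and 343, overlapped between the numbers. BCAT4, an enzyme of glucosinolate synthesis, had 1491 and 7214 against 2851 and 7401. The senescence regulator WRKY53 had 50.8 and 172 against 83.8 and 270. COR47 differed by 0.76 on the log2 scale, PSAE-1 by 0.54, and the median of the photosynthesis list by 0.37. COR47 and PSAE-1 overlapped between the numbers. They had 1247 and 11740 on wild type replicate 2 but 1357 and 12157 on KO-nudx19 replicate 1. Lower on the arrays numbered 2 were MCCA of the starvation list, at 214 and 98.3 in wild type and 255 and 101 in KO-nudx19, and the sucrose transporter gene SWEET11, at 2204 and 1404 against 2147 and 1408. Of the 65 plastid-encoded probe sets, 33 were called lower and 1 higher on the arrays numbered 2. Their median signal was 2508 and 556 in wild type but 1933 and 2197 in KO-nudx19. The number of probe sets called ranged from 704 to 2034 over the other scalings, floors and filters run, except that without a filter on dim probe sets limma called 0, with 2705 at an unadjusted p under 0.05.

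**Figure D3:**
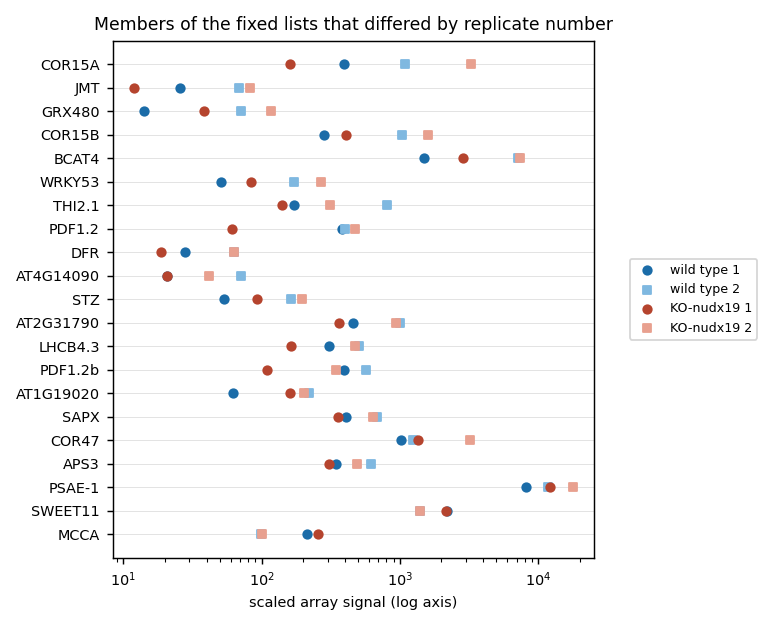
Scaled signal (log axis) of the 21 list members that passed the limma test for the replicate number, with 1 point per array; blue is wild type, red KO-nudx19, circles replicate 1 and squares replicate 2. For most genes the squares lie to the right of the circles, as for COR15A at 1081 and 3246 against 395 and 159, and for MCCA and SWEET11 they lie to the left.

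The genotype difference was therefore also taken within each replicate number. Over all tested probe sets, the differences between KO-nudx19 and wild type for the arrays numbered 1 and for those numbered 2 had a correlation of −0.04 (across probe sets, which are not independent replicates). A difference of at least 2-fold in the same direction in both was seen for 11 probe sets, 7 higher and 4 lower in KO-nudx19, and in opposite directions for 22. Among the 11, singled out after their values were seen, were the calmodulin-like gene CML41, with log2 differences of 1.26 and 1.22 for the arrays numbered 1 and 2, ZCF37, at 30.1 and 42.2 against 69.5 and 89.0, AT4G11290, at 169 and 52.2 against 72.6 and 17.5, and AT3G09860, at 65.5 and 139 against 24.1 and 67.8. With the replicate number as a block, limma called 2 probe sets, both unnamed here, 1 higher in KO-nudx19 (log2 difference 1.56, block adjusted p = 0.0459) and 1 lower (−1.59, block adjusted p = 0.0459). The photosynthesis list had a block adjusted p of 1.7e-05 in camera. Its call was lost without the block at an estimated correlation (0.70 between genes, adjusted p = 0.663). That estimate also holds the list's shift between the numbers (median 0.37), and an estimated correlation was not run with the block. With the block after quantile normalization its median was −0.015 (adjusted p = 0.701).

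**Figure D4:**
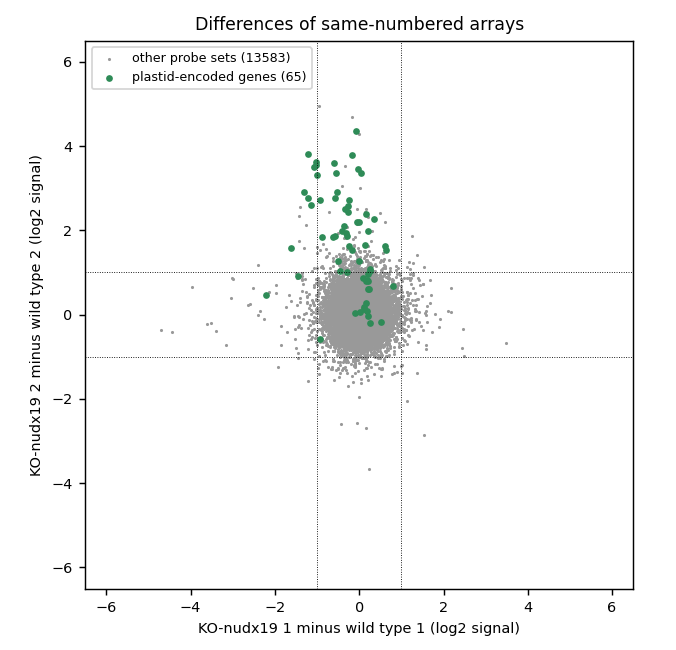
Log2 difference between KO-nudx19 and wild type for the arrays numbered 1 (horizontal axis) and numbered 2 (vertical axis), with 1 point per probe set, plastid-encoded genes in green and dotted lines at 2-fold. The points show no common slope (correlation −0.04), and the plastid-encoded genes lie high on the vertical axis with a median of 1.83 and near or below 0 on the horizontal axis with a median of −0.18.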

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

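All tests of explanations in this part were chosen after the result they concern was seen.

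The hybridisation controls, which entered no comparison, were higher on both KO-nudx19 arrays than on both wild-type arrays for all 18 of their probe sets, with a mean log2 difference of 1.12 (0.76 between the arrays numbered 1 and 1.47 between those numbered 2). The 25S ribosomal RNA control had signals of 1781 and 748 in wild type and 971 and 856 in KO-nudx19.

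The photosynthesis list was higher on the KO-nudx19 arrays. A scale difference of the brightest probe sets stays open: the list's median of 0.39 lay at percentile 69.4 of 10000 random lists matched on mean signal (median 0.36, 95% between 0.17 and 0.49), but the 197 probe sets drawn from had a median of 0.20, 131 of them were unnamed and can hold unnamed photosynthesis or plastid-encoded genes, and 2 were lower by 2-fold on wild type replicate 2 than on each other array. Among 121 nucleus-encoded probe sets of 1 named gene the list lay at percentile 98.7 (random median 0.15), but these were dimmer than the list, with a median signal of 5290 against 9379. The 99th percentile of signal was 3995 and 4533 on the wild-type arrays and 4372 and 4988 on the KO-nudx19 arrays. It overlapped between the genotypes but was higher in KO-nudx19 within each replicate number. The highest signal, 15310 and 19383 in wild type against 20502 and 28796 in KO-nudx19, did not overlap. After quantile normalization the list's median was −0.015 (SD 0.19 over the 9 members), and an effect of the absence of NUDX19 cannot be told apart from the scale of the arrays with these values, because brightness and list membership go together.

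Plastid-encoded transcripts were low on wild type replicate 2. More degraded RNA there than on KO-nudx19 replicate 2, where these transcripts were not as low, is argued against for the 3 control transcripts. Their 3′/5′ ratios were lower on wild type replicate 2, by a mean log2 difference of −0.32 (SD 0.10 over 3 controls). Against the arrays numbered 1 the question stays open. Actin stood at 4.27 against 2.30 and 2.92 and GAPDH at 1.15 against 1.01 and 0.986, but ubiquitin at 1.44 against 1.53 and 1.48. None of the 3 controls is plastid-encoded, so the integrity of plastid RNA was not measured. An effect of the absence of NUDX19 shared by both pairs is argued against, since the pair of arrays numbered 1 had a median difference of −0.18 (SD 0.60 over 65 probe sets) against 1.83 in the other pair. With 1 array per genotype and number, an effect limited to the arrays numbered 2 cannot be told apart from an outlying wild type replicate 2. Less target made from organelle RNA on that array stays open: 7 of 10 mitochondrion-encoded probe sets were also lowest there, against 26.1% of the other tested probe sets (exact binomial test over probe sets, which are not independent, two-sided p = 0.0046), but only 1 of the 10 by 2-fold. Their median signal of 62.1 there was close to the 61.5 on KO-nudx19 replicate 1, and their median shift was 1.57-fold against 4.09-fold for plastid-encoded genes.

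The arrays parted by replicate number: 400 probe sets lay apart by at least 2-fold along it, against 2 along the genotype and 6 along the remaining split of the 4 arrays, which points to a structure of the samples. Separate target preparation may account for it, as the poly(A) controls differed by 2.38 on the log2 scale between the arrays numbered 1 and 2, but these controls mark the batch without showing what else it changed. More degraded RNA could also contribute, since 2 of the 3 control transcripts had a higher 3′/5′ ratio on both arrays numbered 2, and the ubiquitin ratio did not. Plants in another state of stress response were not tested independently: 83.3% of the 12 tested members of the cold, jasmonate, dehydration, oxidative stress and salicylic acid lists were called higher on the arrays numbered 2 by limma, but these lists were picked after their calls were seen, and of the 45 tested members of the other fixed lists 9 were called higher and 2 lower. The labels do not say whether same-numbered arrays shared growth, harvest or preparation, so these explanations cannot be told apart, and the design names no biological difference between the numbers.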

How the results depend on the processing

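Quantile normalization with the replicate block, all runs on added lists and on the replicate number, and leaving out arrays for the RNA ratios were chosen after seeing the data. The count of 0 probe sets changed between the genotypes held in limma under 12 alternatives (51 to 562 at an unadjusted p under 0.05). Same-numbered arrays deviated together (correlation 0.553 over probe sets), and with the replicate block limma called 2 probe sets, and 93 with quantile normalization added. The block alone changed no call of a fixed list or named gene, and together with quantile normalization it brought 7 named genes past the threshold. Leaving out each array gave 0 to 10 calls, the 10 without wild type replicate 1, of which 7 were plastid-encoded genes. These fits assume that the lone array left varies like the other genotype's.

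The number of fixed lists past the test was 1, and 0 with an estimated correlation, with fry, without a filter, with quantile normalization and with that and the replicate block, and 0 to 1 leaving out arrays. The median of the photosynthesis list was −0.015 with quantile normalization, with or without the replicate block. It stayed at 0.39 but did not pass with an estimated correlation, with fry and without a filter, and ranged from 0.18 to 0.59 leaving out arrays. Over all its alternatives the adjusted p ranged from 1.7e-05 to 0.843. RCA turned to −0.015 and LHCB4.2 to −0.059 with quantile normalization, with or without the block, which brings the brightest probe sets of the arrays to common values. The plastid list stayed at 0.75 but did not pass with an estimated correlation or fry, and ranged from −0.14 to 1.86 leaving out arrays (adjusted p from 2.2e-81 to 0.828 over its alternatives). Among the 24 genes named by rule, no other gene changed its direction.

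Probe sets apart by 2-fold numbered 2, and 1 with the higher floor, 0 with the pseudocount, with the stricter filter and with 1 probe set per named gene, 28 without a filter, and 85 to 156 leaving out arrays, where fewer arrays must lie apart. The ubiquitin ratio's log2 difference moved to −0.0094 with quantile normalization. Of the lists that did not pass, the UDP-glycosyltransferases did with the stricter filter (adjusted p = 0.0482, range 0.0482 to 0.750 over their alternatives), and several added ones with an array left out (adjusted p down to 0.0016, mitochondrion-encoded genes without wild type replicate 1), and directions turned: the NADPH-producing enzymes ranged from −0.18 to 0.013 leaving out arrays, mitochondrion-encoded genes from −0.34 to 0.53, cytochrome P450s from −0.18 to 0.041 (0.013 with the higher floor), beta-glucosidases from −0.20 to 0.042, SWEET genes from −0.53 to 0.069, and expansins and xyloglucan endotransglucosylases from −0.23 to 0.056 (−0.031 with quantile normalization, with or without the block, and −0.15 with the stricter filter). Where no cause is given, the cause was not tested. The alternatives for NUDX19 gave no value, as it has no named probe set, and robust eBayes was not run for lists, which camera does not use. The results cover only the brighter probe sets, since the filter, set beforehand at the 40th percentile of mean signal, left the dimmer ones out.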

Other observations

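The lists and genes in this part were chosen after seeing the data, and no explanation was tested for them. Among the gene families added by symbol and reported here, none passed camera's test between the genotypes. The 23 tested UDP-glycosyltransferases had a median log2 difference of −0.08, with 6 whose arrays did not overlap, all lower in KO-nudx19 (camera of limma, adjusted p = 0.0934, and 0.0482 with the stricter filter on dim probe sets). The 14 serine carboxypeptidase-like genes had a median of −0.16, with 4 lower and 1 higher that did not overlap (adjusted p = 0.0934). For comparison, 22.3% of all tested probe sets did not overlap between the genotypes. Medians were −0.20 for 9 SWEET sugar transporters (adjusted p = 0.226), −0.14 for 8 beta-glucosidases (0.418), 0.05 for 13 expansins and xyloglucan endotransglucosylases, whose mean was −0.06 (0.418), −0.01 for 15 cytochrome P450s (0.837) and 0.15 for 10 mitochondrion-encoded genes (0.226). The 4 tested tau-class glutathione S-transferases were too few for the test and had a median of 0.13. With an estimated correlation the lowest adjusted p among all added lists was 0.509.

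Several single genes differed widely between the arrays numbered 2 and 1. CSLA01, a cellulose synthase-like gene, had 25.9 and 212 in wild type and 1.82 and 204 in KO-nudx19 (replicates 1 and 2), TBL26 had 67.0 and 419 against 33.9 and 678, and the expansin gene EXPA16 had 18.5 and 66.6 against 9.30 and 183. AT1G19960 had 242 and 1135 in wild type and 230 and 1875 in KO-nudx19. In the other direction, AT1G67870 had 1306 and 215 against 1485 and 213, AT1G70620 had 381 and 36.3 against 357 and 87.4, and the plastid genes atpA and psaA had 4070 and 84.3 and 471 and 55.6 in wild type against 1333 and 251 and 247 and 37.1 in KO-nudx19. All passed the limma test for the replicate number.

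Quantile normalization together with the replicate block called 93 probe sets in limma, 59 higher and 34 lower in KO-nudx19, and 26 of them were named plastid-encoded genes. In 59 of the 93 both pairs had the same direction, and 8 differed by at least 2-fold in both. That fit has 1 residual degree of freedom and an infinite prior, so it takes the spread of each probe set from the trend over all probe sets and not from its own arrays, and its adjusted p-values carry that limit. PDF1.2b had an adjusted p of 1.4e-04 in that fit, AT5G48210 4.8e-04, AT5G64120 0.0124, COR47 0.0175, AT3G59780 0.0197, PME61 0.0224 and AT5G47050 0.0478. Over the other alternatives none of these 7 genes passed.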
